A study of Arabidopsis thaliana with 12 samples.

How the data were processed

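Shoots of Arabidopsis thaliana (accession Col-0), 4 weeks old and grown on soil, were compared with and without UV-B on 12 one-colour Agilent arrays, each hybridised with Cy3-labelled RNA from a single sample. The 4 groups, each of 3 arrays, were control and UV-B plants at a mid and at a late time point. Per the labels' protocols, a biologically effective UV-B dose of 1.31 kJ m-2, weighted with a plant action spectrum normalised at 300 nm, was given over 4 h together with visible light (400 to 700 nm) at 140 µmol m-2 s-1. The labels give the same visible light for the control plants. The labels of the UV-B samples read 4 h for mid and 8 h for late exposure, whereas the series text dates the harvests 4 h and 8 h after exposure. Which of these the time points mean could not be settled, so only mid and late are used here. The replicates are numbered in the titles, but the labels do not say whether they came from separate plants or pools, so p-values measure the spread between these arrays, part of which may be technical.

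The deposited scanner files hold spot intensities on a linear scale that Feature Extraction 10.7.3.1 produced, per the file headers. The column used, gProcessedSignal, is the intensity after the scanner software's own background treatment, per the file headers. No column of mean spot signals was used, because the files examined gave median spot signals and median backgrounds. The alternative with normexp background correction (offset 50) therefore took the median spot signal. A table of the authors' processed values was also deposited on a log2 scale. The authors' log2 values could be rebuilt from the scanner intensities as log2 intensity minus each array's 75th percentile, centred on each probe's median over the arrays, with at least 99.9% of probes within 0.005. Scale, centring and direction of that table are thereby settled, its lowest correlation with the rebuilt values was 0.99995 across probes, and its column medians ran from -0.115 to 0.153. Which software the authors used for that step is not given in the sources used here.

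Each array held 62976 spots, of which 61657 were not controls, for 43603 probes. Control spots and spots marked as outliers (4 to 24 per array) were left out, and 0 spots were saturated. The spots of a probe were averaged on the log2 scale, and the array's 75th percentile was subtracted. Of the probes, 36098 carry a RefSeq transcript accession, and 34285 (78.6%) were matched without version numbers to 25383 loci of a RefSeq gene table of the TAIR10.1 assembly. The other 9318 probes were not assigned to a locus. Because the array design names no build of its own, no coordinates are given. For 6919 loci with several probes, the probe with the highest mean over the 12 arrays stood for the gene. A gene was tested where that probe was well above background on all 3 arrays of at least 1 group, which left 19238 genes.

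Signal over background sets the precision on arrays, along with their number. The 75th percentile of the intensity ran from 742 to 1516, the median from 95.97 to 210.6, the local background from 24 to 26, and the share of spots well above background from 67.3% to 71.7%. Replicate spots of a probe had a median coefficient of variation of 3.89% to 7.28%. Correlations between arrays of a group, across genes, lay between 0.977 and 0.995. With 3 arrays per group, their number limits the precision of every difference.

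All comparisons came from limma 3.58.1 (R 4.3.3, lmFit and eBayes) with group means over all 12 arrays, which share an estimate of the spread, and with two-sided p-values adjusted by Benjamini-Hochberg over the genes tested, at a threshold of 0.05. The comparisons were UV-B against control at mid, the same at late, the difference between these effects, and control late against control mid. The mean of the mid and late effects was tested too. A gene not well above background on any array of a group has only a bound there. It is given as at least N-fold, the bright group's mean against, per array of the dim group, the higher of the gene's own signal and the lowest signal among probes well above background.

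A set of 28 gene lists with 475 loci was fixed before the data were examined, as were the groups, the test, the alternatives and the rule for named genes. The lists cover UV-B receptor signalling, flavonoids and anthocyanins, phenylpropanoids, photoprotection, DNA repair, cell cycle, oxidative stress, salicylate defence, jasmonate, ethylene, camalexin and indole compounds, aliphatic glucosinolates, photosynthesis, chlorophyll synthesis, heat shock, unfolded protein response, abscisic acid with drought and cold, the circadian clock, auxin and growth, senescence and cuticular wax. Further lists hold markers of flowers, roots, seeds, epidermis and guard cells, vascular tissue and meristem, and reference genes. Lists with at least 3 tested members, 26 of them, were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry.

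The rule named 6 check genes (HY5, RUP2, CHS, ELIP1, UVR8 and PR1), the 6 highest and 6 lowest changes per UV-B comparison whose arrays lay outside the range of the controls, and up to 3 rising and 3 falling members of each list. It further named the 5 highest and 5 lowest differences between times, and the 4 highest and 4 lowest changes between the controls with members of the clock list. The text names only part of the genes that this rule gives.

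The slide and the scan date of the arrays went together. Slide 1 held replicates 1 and 2 of all 4 groups, slide 2 held replicate 3 of all groups except UV-B mid, and slide 3 held UV-B mid replicate 3 alone. UV-B arrays lay in row 1 of a slide and control arrays in row 2, except UV-B mid replicate 3 in row 2, so an estimate of a row effect rests on that array alone. Slide was tested as a fixed block, as a random block and within slide 1. As a fixed block it leaves UV-B mid replicate 3, alone on its slide, without weight in the comparisons.

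Deviations from the group means were compared between arrays with the same replicate number. At late the correlations of control with UV-B were 0.21, 0.50 and 0.24, and between the controls of both times they were 0.11, 0.44 and 0.40. All of these lie above the limit of 0.1, so the numbers were taken to pair these groups, on the evidence of the data and not of the labels. The highest correlations with another number were -0.03, -0.03 and 0.21 at late and 0.13, 0.04 and -0.10 between the controls. Replicate 1 of the controls was thus no closer to its own number. Numbers 1 and 2 share slide 1 and number 3 slide 2, and slide and array brightness may contribute. The correlations therefore do not show that the samples themselves were paired. At mid the correlations were -0.32, -0.01 and -0.19, so these numbers do not pair the samples. The other alternatives were quantile or median scaling, the authors' table, no filter or a stricter filter, the mean over probes, limma with trend and robust settings, a fit of only the groups compared, the slide row, the replicate number as a block, at least a 2-fold change, and leaving out each array in turn. The array brightness as a covariate and the replicate block with only the groups compared were added after the data had been examined, as were all settings for the lists of the difference and of the controls and for most named genes of the difference.

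The steps were tested on simulated data for the mid comparison with 19238 genes, in which 50 genes each were changed by 0.5, 1, 2 or 4 on the log2 scale. The test recovered 16%, 64%, 88% and 100% of them with the right sign, called 10 unchanged genes, and had a median error of 0.12. Far fewer genes were changed there than the 8290 called at mid in the data, which makes the Benjamini-Hochberg threshold stricter. These shares therefore do not give the recovery in the data. In a simulation of the late comparison, a jasmonate list shifted by 0.5 was called and 0 of the other lists were. The simulated genes were drawn independently of each other, so this does not show how often lists of correlated genes are called falsely. Tables and plots were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.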

Results

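Transcript levels were measured in shoots of Arabidopsis plants that had received UV-B together with visible light and in control plants, at a mid and a late time point, with 3 arrays in each of the 4 groups. Per the labels, the control plants had the same visible light. UV-B is the short-wave part of sunlight that plants sense through the photoreceptor UVR8 and that damages DNA. Of the genes on the array, 19238 were bright enough to be tested. The array intensity at the 75th percentile ran from 742 to 1516, and between 67.3% and 71.7% of spots were well above background. The main axis of a principal component analysis held 48.1% of the variance and the next 26.7%. Values are log2 differences between group means with the standard error from limma, over 3 arrays per group unless stated otherwise.

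The first comparison asked which transcripts differed between UV-B and control plants at the mid time point. Genes of UV-B perception and of the flavonoid pathway rose strongly. ELIP2, which encodes an early light-induced protein of the thylakoid, rose by 10.09 ± 0.22 (adjusted p = 6.6e-11), and its relative ELIP1 by 6.98 ± 0.19. The transcription factor gene HY5 rose by 4.14 ± 0.14, RUP2, a repressor of UVR8 signalling, by 3.97 ± 0.20, and CHS, the gene of chalcone synthase, the entry enzyme of flavonoid synthesis, by 5.31 ± 0.15. Auxin genes were among those that fell most: IAA29 changed by -6.31 ± 0.33 (adjusted p = 9.3e-08), and YUC8 and YUC9, which encode enzymes of auxin synthesis, fell at least 12.9-fold each, to a level not well above background on any UV-B array. The photoreceptor gene UVR8 itself did not pass, at -0.31 ± 0.17 (adjusted p = 0.159).

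Among the other genes with the highest changes at mid were AT2G23910 (9.39 ± 0.18), the glycosyltransferase genes UGT84A1 (8.40 ± 0.18) and UGT78D3 (8.07 ± 0.27, well above background on 2 of the 3 control arrays) and AT3G62990 (7.36 ± 0.20). AT3G24750 was not well above background in the controls and rose at least 61.1-fold. Among those with the lowest changes, AT5G62280 fell at least 18.9-fold, AT3G21330 at least 16.2-fold and CYP96A5 at least 11-fold, each to a level not well above background in the UV-B plants.

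In total 8290 genes (43.1% of those tested) changed at mid, 4144 higher and 4146 lower (50% higher, but 59.1% with scaling to the median), and 3181 of them by at least 2-fold (1553 higher and 1628 lower). An unadjusted p under 0.05 was reached by 9712 genes. With slide as a block the count was 7442, and within slide 1, with 2 arrays per group, it was 6587. With the slide row as a covariate, whose estimate rests on UV-B mid replicate 3 alone, it was 4642. Slide 3 held UV-B arrays only and slide 2 no UV-B array of this time, so neither gives a value for mid.

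Of 16 tested genes of UV-B receptor signalling, 15 rose and 1 did not pass at mid (median 2.87, adjusted p = 1.6e-12), with RUP1 at 4.67 ± 0.17. In the flavonoid and anthocyanin list 22 of 25 genes rose, 1 fell and 2 did not pass (median 4.77, adjusted p = 3.8e-18), with F3H, the gene of flavanone 3-hydroxylase, at 7.35 ± 0.13. The gene that fell was TTG1, a regulator of the pathway, at -0.47 ± 0.17. Its call was lost when any of 9 arrays was left out (control mid 1 or 2, UV-B mid 1 or 2, control late 1, 2 or 3, or UV-B late 2 or 3), with changes between -0.47 and -0.31. Phenylpropanoid genes rose in 15 of 20 cases, 1 fell and 4 did not pass (median 1.49, adjusted p = 2.9e-09), with 4CL3 at 5.89 ± 0.13, PAL1 at 5.10 ± 0.19 and PAL2 at 5.03 ± 0.19. SNG1, which acts in sinapate ester synthesis, fell by 0.54 on the log2 scale, a call lost without control mid replicate 1 (-0.38) or UV-B mid replicate 3 (-0.48), with slide as a block (-0.50) and within slide 1 (-0.60). Of the photoprotection list, which holds carotenoid, tocopherol, ascorbate and vitamin B6 genes, 19 of 22 rose, 1 fell and 2 did not pass (median 0.90, adjusted p = 5.6e-08). BCH1, a beta-carotene hydroxylase gene, stood at 3.5 ± 0.17 and PDX1.1, of vitamin B6 synthesis, at 2.93 ± 0.14. PDX1.2 fell by 0.81 on the log2 scale, and its call was lost without control mid replicate 3 (-0.64), with slide as a block (-0.73) and within slide 1 (-0.57). The shifts of these 4 lists held with an estimated correlation between genes, where the adjusted p were 0.0072, 0.021, 0.012 and 0.0070 in the order given. No other list passed with an estimated correlation at mid. The fry test, which asks whether the genes of a list move one way on balance and compares them with no other genes, called 17 lists at mid. These were the 13 called by camera and also chlorophyll synthesis as higher (adjusted p = 0.013) and senescence (0.043), wax (0.027) and reference genes (6.4e-04) as lower.

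DNA repair genes were higher in 10 of 23 cases at mid and 13 did not pass (median 0.36, or 0.22 with normexp background correction, adjusted p = 0.0041, and adjusted p = 0.40 with an estimated correlation). The photolyase genes UVR3 (2.99 ± 0.18) and PHR1 (2.61 ± 0.13) and the damage recognition gene DDB2 (2.89 ± 0.18) led them. Clock genes rose in 12 of 21 cases, 2 fell and 7 did not pass (median 0.89, adjusted p = 0.0025, and adjusted p = 0.21 with an estimated correlation). ELF4 (1.70 ± 0.18), GI (1.64 ± 0.18) and PRR5 (1.39 ± 0.21) rose, and RVE1 (-1.14 ± 0.23) and CHE (-0.91 ± 0.21) fell, CHE with its call lost within slide 1 (-0.79). Of 20 cell cycle genes 4 rose, among them E2FA (0.76 ± 0.16), CDC6 (0.59 ± 0.10) and MCM3 (0.65 ± 0.24), and 16 did not pass (median 0.22, adjusted p = 0.047, and adjusted p = 0.53 with an estimated correlation). The call of MCM3 was lost without control mid replicate 2 or 3, UV-B mid replicate 2 or 3, control late replicate 1, 2 or 3, or UV-B late replicate 2 or 3 (0.41 to 0.75), with slide as a block (0.38) and within slide 1 (0.23). The call of the cell cycle list was lost without control mid replicate 3 (adjusted p = 0.16), UV-B mid replicate 2 (0.060), UV-B mid replicate 3 (0.14) or UV-B late replicate 1 (0.052), with slide as a block (0.22), within slide 1 (0.35), with normexp (0.065) and among genes well above background on all 12 arrays (0.052).

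**Figure D1:**
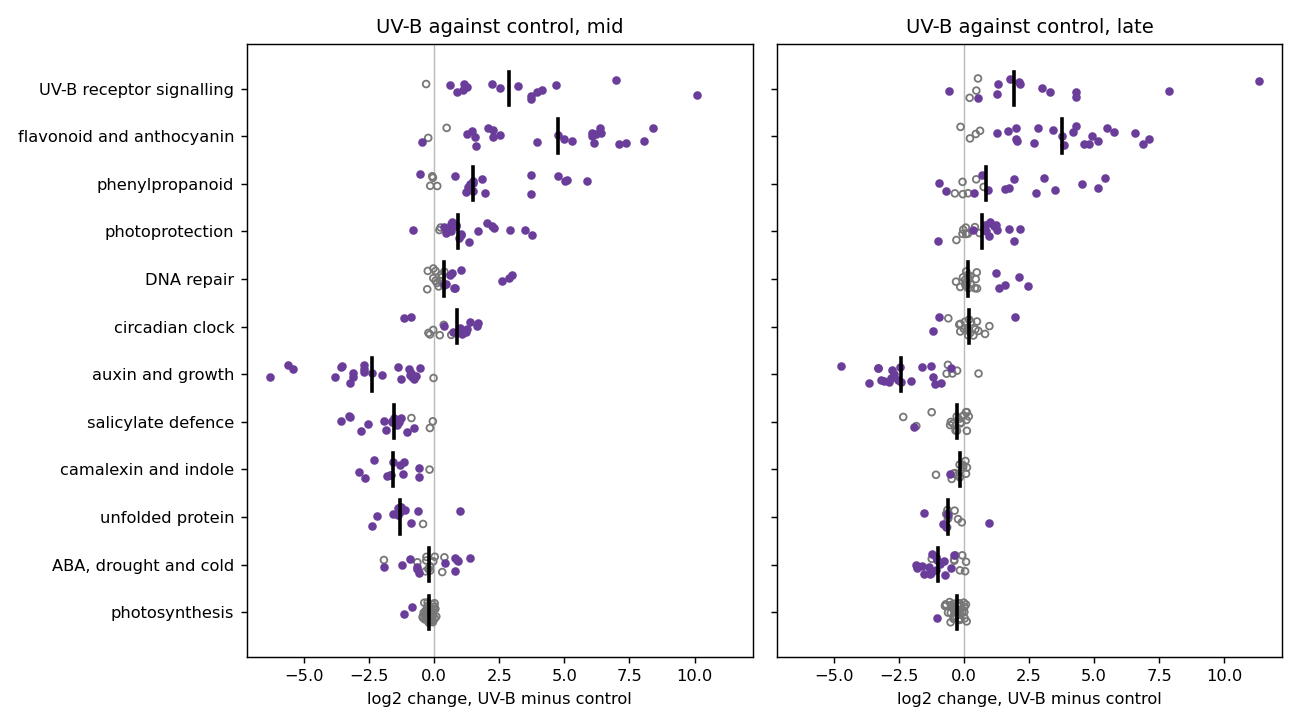
Log2 change, UV-B minus control, of each tested gene in 12 gene lists at mid (left) and late (right), where a dot is a gene, filled where its adjusted p was under 0.05 and open where not, and a black bar is the list's median. The flavonoid list had its median at 4.77 at mid and 3.78 at late, and the auxin and growth list at -2.37 and -2.41.

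Auxin and growth genes fell together at mid: 24 of 25 fell, 0 rose and 1 did not pass (median -2.37, adjusted p = 1.2e-13, and adjusted p = 0.067 with an estimated correlation). Salicylate defence genes fell in 16 of 19 cases and 3 did not pass (median -1.54, adjusted p = 1.6e-05, and adjusted p = 0.45 with an estimated correlation), with UV-B mid replicate 3 apart from the others (list median -0.72 against -2.03 and -1.71). WRKY38 stood at -3.60 ± 0.46 and ALD1, of pipecolic acid synthesis, at -3.28 ± 0.76. PR1, a marker of salicylate defence, fell by 3.22 on the log2 scale (SE 0.97, adjusted p = 0.019). Its call was lost without control mid replicate 3 (-2.67), UV-B mid replicate 1 (-2.54) or UV-B mid replicate 2 (-2.57). Camalexin and indole genes fell in 12 of 13 cases and 1 did not pass (median -1.57, adjusted p = 1.1e-06, and adjusted p = 0.081 with an estimated correlation), with PAD3, of camalexin synthesis, at -2.89 ± 0.36 and MYB51 at -2.33 ± 0.21. Genes of endoplasmic reticulum chaperones and the unfolded protein response fell in 12 of 14 cases, 1 rose and 1 did not pass (median -1.30, adjusted p = 4.5e-05, and adjusted p = 0.40 with an estimated correlation). Here too UV-B mid replicate 3 stood apart (-0.73 against -1.63 and -1.56). TIN1 stood at -2.39 ± 0.31 and BIP3 at -2.20 ± 0.45, and NAC103, a transcription factor gene, was the member that rose (0.98 ± 0.27). Ethylene genes fell in 8 of 11 cases and 3 did not pass (median -0.88, adjusted p = 0.0017, and adjusted p = 0.17 with an estimated correlation), led by ERF1 at -2.91 ± 0.29. Jasmonate genes fell in 12 of 24 cases, 3 rose and 9 did not pass (median -0.49, adjusted p = 0.024, and adjusted p = 0.45 with an estimated correlation). AOC1, of jasmonate synthesis, fell by 2.02 on the log2 scale, whereas LOX3 rose by 1.3. The call of the jasmonate list was lost without control mid replicate 2 (adjusted p = 0.0502) or UV-B mid replicate 3 (0.0503) and within slide 1 (0.066).

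The other lists were not shifted at mid. Of 24 oxidative stress genes 8 rose, 11 fell and 5 did not pass (adjusted p = 0.63), with ZAT12 (2.57) and CAT2 (1.41) among the first and GSTF7 (-2.75) among the second. Of 17 heat shock genes 7 rose, 6 fell and 4 did not pass (adjusted p = 0.67), with DREB2A at 3.14 and HSFB2A at -1.95; the median (-0.20) and the mean (0.31) of this list differ in sign. Abscisic acid, drought and cold genes rose in 6 of 24 cases, fell in 6 and did not pass in 12 (adjusted p = 0.57), with COR15A at 1.36 and the cold regulator CBF1 at -1.92. Wax genes rose in 3 of 14 cases, fell in 5 and did not pass in 6 (adjusted p = 0.46), with CER3 at 1.44 and CER4 at -2.36. Chlorophyll synthesis genes rose in 6 of 15 cases, fell in 3 and did not pass in 6 (adjusted p = 0.21), with CHLH at 1.27 and PORA at -1.14. Senescence genes rose in 1 of 12 cases, fell in 4 and did not pass in 7 (adjusted p = 0.15), with NYC1 at 1.41 and SEN1 at -2.88; within slide 1 the list passed (adjusted p = 0.045), as it did with slide as a block (adjusted p = 0.047). Of 37 photosynthesis genes 2 fell, LHCB4.2 (-1.18) and LHCB2.1 (-0.86), and 35 did not pass (adjusted p = 0.11). Within slide 1 both genes lost their call (-1.08 and -0.86). This list passed as lower without UV-B late replicate 1 (adjusted p = 0.032), UV-B mid replicate 1 (0.040), control mid replicate 1 (0.046) or control mid replicate 2 (0.025). It did so too with quantile scaling (adjusted p = 0.0073), the mean over probes (0.032), only the mid groups in the model (0.029) and array brightness as a covariate (6.0e-04). Of 13 aliphatic glucosinolate genes UGT74C1 (0.52) rose and 12 did not pass (adjusted p = 0.58). Its call was lost without control mid replicate 2 (0.49) or 3 (0.46) or UV-B mid replicate 1 (0.52) or 2 (0.54), with slide as a block (0.55) and within slide 1 (0.46).

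Markers of other organs and cell types moved little at mid. Of 8 epidermis and guard cell markers 2 rose, MUTE (0.67 ± 0.17) and SPCH (0.65 ± 0.20), and 6 did not pass (adjusted p = 0.64). Of 7 vascular markers SUC2 (-0.39 ± 0.14) fell and 6 did not pass (adjusted p = 0.64). None of the 4 root markers (adjusted p = 0.63) or 3 meristem markers (adjusted p = 0.67) passed. The call of SPCH was lost without control mid replicate 1 or 3 or UV-B mid replicate 1 or 2 (0.48 to 0.65), with slide as a block (0.65) and within slide 1 (0.62). That of SUC2 was lost without control mid replicate 1 or 3, UV-B mid replicate 1, 2 or 3, or control late replicate 2 or 3 (-0.42 to -0.33), with slide as a block (-0.43) and within slide 1 (-0.34). The floral marker AG (0.37 ± 0.36) and the seed marker CRU3 (-0.33 ± 0.32) were the only members of their lists bright enough to test, and neither passed. Of 9 reference genes ACT8 (-0.82 ± 0.31) and UBQ10 (-0.46 ± 0.16) fell and 7 did not pass (adjusted p = 0.24). The call of ACT8 was lost when any of 8 arrays was left out (control mid 1 or 2, UV-B mid 1, control late 1, 2 or 3, or UV-B late 2 or 3; -0.82 to -0.40), and that of UBQ10 without any of 6 (control mid 1, 2 or 3, UV-B mid 1 or 2, or control late 3; -0.52 to -0.34).

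Named genes at mid that lost their call with the slide row as a covariate were PR1, TTG1, SNG1, ALD1, UGT74C1, LHCB4.2, LHCB2.1, PDX1.2, NAC103, BIP3, COR15A, RVE1, MUTE, SPCH, SUC2, ACT8 and UBQ10, while UVR8 (-0.72) passed. With normexp NAC103 and SPCH lost it, with scaling to the median TTG1, SNG1, SUC2, ACT8 and UBQ10, and with quantile scaling UGT74C1. With no filter on dim probes TTG1, MCM3, SUC2, ACT8 and UBQ10 lost it, with the mean over probes SUC2, and in a fit of only the mid groups TTG1, MCM3, ACT8 and UBQ10. ACT8 lost it within slide 1 (-1.18) and with slide as a random block (-0.81). Some log2 changes kept their call and moved by over 1.5 times: those of TTG1 with slide as a block (-0.71) and within slide 1 (-0.75), E2FA within slide 1 (0.48), NAC103 without control mid replicate 1 (0.65), LOX3 (0.84) and PORA (-1.85) with the mean over probes, RVE1 (-0.66) and MUTE (0.39) with normexp, and MCM3 with the slide row (1.00).

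Adjusted over the list alone, the mid counts were the same except that 2 cell cycle genes rose, 17 salicylate, 14 jasmonate, 9 ethylene and 7 wax genes fell, 8 chlorophyll synthesis genes rose, 1 photosynthesis gene fell, and 0 aliphatic glucosinolate, vascular and reference genes passed. With slide as a block the medians of the shifted lists at mid were 2.98 for UV-B receptor signalling, 4.98 for flavonoids, 1.44 for phenylpropanoids, 0.92 for photoprotection, 0.34 for DNA repair, 0.81 for the clock, 0.13 for the cell cycle, -2.47 for auxin, -2.05 for salicylate, -1.74 for camalexin, -1.60 for unfolded protein, -1.01 for ethylene and -0.58 for jasmonate genes. Within slide 1 they were 3.16, 5.07, 1.43, 0.85, 0.31, 0.75, 0.14, -2.41, -2.00, -1.66, -1.50, -0.94 and -0.54 in the same order.

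**Figure D2:**
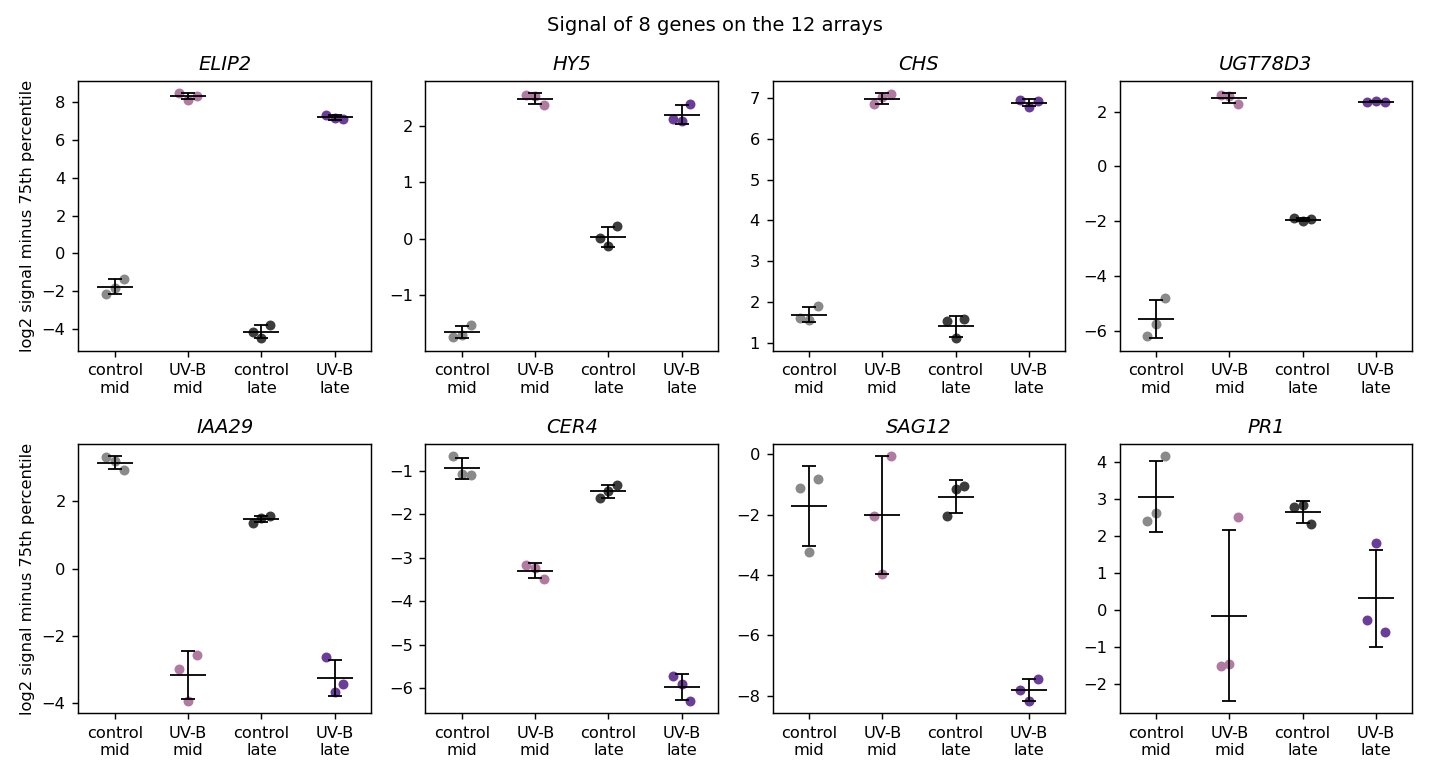
Signal of 8 genes in the 4 groups, as log2 intensity minus the array's 75th percentile, where a dot is an array, a black bar the mean of 3 arrays and the error bar their SD. ELIP2, HY5, CHS and UGT78D3 lay higher and IAA29 and CER4 lower in UV-B than in control plants on every array of both times, whereas the arrays of PR1 overlapped between the groups at mid.

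The second comparison asked the same at the late time point. Several genes of UV-B responses that had risen at mid also rose at late: ELIP2 rose by 11.35 ± 0.22 (adjusted p = 9.1e-11), ELIP1 by 7.89 ± 0.19, CHS by 5.49 ± 0.15, RUP2 by 4.31 ± 0.20 and HY5 by 2.17 ± 0.14. UGT84A1 (7.12 ± 0.18), TT7, the gene of flavonoid 3'-hydroxylase (6.90 ± 0.14), and AT5G62210 (6.79 ± 0.23) followed, and AT3G24750 rose at least 31.3-fold from a level not well above background. SAG12, a protease gene used as a marker of senescence, fell at least 23.7-fold and was not well above background on any of the 3 UV-B arrays, and AT4G12510 fell at least 14.1-fold to such a level. IAA29 (-4.71 ± 0.33), CER4, of wax alcohol synthesis (-4.50 ± 0.18, well above background on 1 of the 3 UV-B arrays), HSD2 (-3.90 ± 0.20, likewise on 1 of 3) and AT5G57760 (-3.78 ± 0.21) also fell.

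At late 4559 genes (23.7%) changed, 2447 higher and 2112 lower, and 1514 of them by at least 2-fold (889 higher and 625 lower). An unadjusted p under 0.05 was reached by 6840. The median SD between replicates was 0.259 in the UV-B late group and 0.149 in the late controls, whereas the fit uses an estimate of the spread shared by all 4 groups. In a fit of only the late groups 3322 genes changed. With slide as a block the count was 4484 and within slide 1 it was 2858, of which 2657 were among the 4559. With the slide row as a covariate, which rests on 1 array, the count was 1369. With array brightness as a covariate, an alternative added after the data had been examined, it was 6947. Slide 2 holds 1 array per group and allows no test of its own.

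UV-B receptor signalling genes rose in 12 of 16 cases at late, 1 fell and 3 did not pass (median 1.94, adjusted p = 2.4e-14). The gene that fell was UVR8 (-0.56 ± 0.17, adjusted p = 0.032), a call lost without control late replicate 1 (-0.48), 2 (-0.59) or 3 (-0.61) or UV-B late replicate 3 (-0.48), and within slide 1 (-0.53). Flavonoid genes rose in 21 of 25 cases and 4 did not pass (median 3.78, adjusted p = 4.5e-27), with F3H at 6.58 ± 0.13. Phenylpropanoid genes rose in 12 of 20 cases, 2 fell and 6 did not pass (median 0.84, adjusted p = 2.4e-08), with PAL2 at 5.43 ± 0.19 and PAL1 at 5.15 ± 0.19, while CAD5 (-0.96 ± 0.15), of lignin synthesis, and 4CL2 (-0.70 ± 0.12) fell. Photoprotection genes rose in 12 of 22 cases, 1 fell and 9 did not pass (median 0.70, adjusted p = 2.9e-05). The tocopherol genes moved apart, with VTE1 at 1.92 ± 0.13 and VTE4 at -0.98 ± 0.15. Auxin and growth genes fell in 20 of 25 cases and 5 did not pass (median -2.41, or -1.62 with 3 dim genes set to their bounds, adjusted p = 3.7e-17). Among them EXPA8, an expansin gene, stood at -3.31 ± 0.35 and YUC8 fell at least 4.55-fold. These 5 lists held with an estimated correlation, with adjusted p of 0.0091, 0.011, 0.012, 0.011 and 0.037 in the order given, and no other list did at late. With normexp the auxin median was -1.22. Fry called 14 lists at late, without unfolded protein (adjusted p = 0.082) and photosynthesis (0.34) and with heat shock as higher (0.015) and ethylene (0.047) and reference genes (0.0037) as lower.

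Abscisic acid, drought and cold genes fell in 16 of 24 cases at late and 8 did not pass (median -0.98, adjusted p = 5.2e-08, and adjusted p = 0.076 with an estimated correlation). RD20 (-1.86 ± 0.22), LEA4-5 (-1.78 ± 0.28) and RD22 (-1.60 ± 0.11), which are known for their response to drought, were the lowest. DNA repair genes rose in 5 of 23 cases and 18 did not pass (median 0.17, adjusted p = 0.0038, and adjusted p = 0.37 with an estimated correlation), with UVR3 at 2.46, DDB2 at 2.1 and PHR1 at 1.57. Chlorophyll synthesis genes rose in 6 of 15 cases and 9 did not pass (median 0.38, adjusted p = 0.014, and adjusted p = 0.33 with an estimated correlation), among them CHLI2 (0.78) and CHLH (0.80), whose call was lost without control late replicate 3 (0.68) or UV-B late replicate 2 (0.74). Wax genes rose in 1 of 14 cases, fell in 6 and did not pass in 7 (median -0.35, adjusted p = 0.0042, and adjusted p = 0.24 with an estimated correlation), with CER3 at 0.96, CER4 at -4.50 and KCS1 at -1.02.

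Jasmonate genes fell in 8 of 24 cases at late and 16 did not pass (median -0.50, adjusted p = 0.018, and adjusted p = 0.46 with an estimated correlation), with CORI3 (-1.68), LOX2 (-1.59) and AOC1 (-1.31) lowest. The list's call was lost without control late replicate 2 (adjusted p = 0.068). Unfolded protein genes fell in 5 of 14 cases, 1 rose and 8 did not pass (median -0.62, adjusted p = 0.0088, and adjusted p = 0.56 with an estimated correlation), a call lost without UV-B late replicate 1 (adjusted p = 0.058). BIP3 (-1.52) fell, a call lost without control late replicate 1 or 2 or UV-B late replicate 1 or 3 (-1.38 to -1.25). NAC103 (0.98) rose, a call lost without control late replicate 2 or 3 or UV-B late replicate 2 or 3 (0.76 to 1.01) and within slide 1 (0.99). Senescence genes fell in 5 of 12 cases and 7 did not pass (median -0.57, adjusted p = 0.023, and adjusted p = 0.53 with an estimated correlation), with ASN1 at -1.27 beside SAG12. The call of the senescence list was lost without UV-B late replicate 1 (adjusted p = 0.18) or control late replicate 2 (0.15), among genes well above background on all 12 arrays (0.16) and with array brightness as a covariate (0.077). Of 37 photosynthesis genes only LHCB2.1 (-1.05) fell and 36 did not pass, yet the list was shifted lower as a whole (median -0.28, adjusted p = 0.0053, and adjusted p = 0.76 with an estimated correlation). Its medians on the UV-B arrays, set against the mean of the late controls, were 0.19, -0.66 and -0.39 in replicates 1, 2 and 3, and on the control arrays 0.11, -0.15 and 0.06, so UV-B late replicate 1 lay above every control. Photosynthesis genes had a median loading of -0.72 on the main axis of spread within groups, which followed array brightness. The list did not pass without UV-B late replicate 2 (adjusted p = 0.28) or within slide 1 (0.094), and without UV-B late replicate 1 its mean moved from -0.31 to -0.55. With the slide row as a covariate, which rests on a single array, the unfolded protein (adjusted p = 0.42), senescence (0.70) and chlorophyll synthesis (0.18) lists lost their calls at late, and the mean of the unfolded protein list turned from -0.51 to 0.19.

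The remaining lists were not shifted at late. Of 19 salicylate genes WRKY38 (-1.91 ± 0.46) fell and 18 did not pass (median -0.27, adjusted p = 0.27). PR1 did not pass at -2.33 ± 0.97 (adjusted p = 0.11), but passed without UV-B mid replicate 3 (adjusted p = 0.018), with slide as a block (0.025), within slide 1 (0.0498) and with only the late groups in the model (0.035). The salicylate list passed as lower without UV-B late replicate 2 (adjusted p = 0.026) and with the replicate number as a block among only the late groups (0.016), and as higher with the slide row as a covariate (0.0051). Of 13 camalexin genes CYP79B2 (-0.52) fell and 12 did not pass (adjusted p = 0.30). The call of CYP79B2 was lost without control mid replicate 2, UV-B mid replicate 1, 2 or 3, control late replicate 1, 2 or 3, or UV-B late replicate 1 or 3 (-0.56 to -0.34) and within slide 1 (-0.37). With slide as a block (adjusted p = 0.060) and with the replicate number as a block (adjusted p = 0.062) its call was lost while the change stayed at -0.52. Of 11 ethylene genes 3 fell, among them ETR2 (-1.28) and EBF2 (-0.57), and 8 did not pass (adjusted p = 0.17). The call of EBF2 was lost without control late replicate 1, 2 or 3 or UV-B late replicate 2 or 3 (-0.60 to -0.43) and within slide 1 (-0.45). Of 24 oxidative stress genes 6 rose, 2 fell and 16 did not pass (adjusted p = 0.70), with ZAT12 at 2.71, CAT2 at 1.32, CAT1 at -0.95 and CAT3 at -0.94. Of 17 heat shock genes 7 rose and 10 did not pass (adjusted p = 0.099), with DREB2A at 2.04, and the list passed without control late replicate 1 (adjusted p = 0.035) and among genes well above background on all 12 arrays (0.030). Of 21 clock genes CCA1 rose (at least 1.96-fold, with 1 of its 3 probes at -0.66), RVE1 (at least 1.38-fold) and CHE (-0.95) fell, and 18 did not pass (adjusted p = 0.38). The call of CCA1 was lost with the mean over its probes (a log2 change of 0.37) and with normexp background correction (0.51), that of RVE1 with normexp (a log2 change of -0.27) and that of CHE within slide 1 (-0.76). None of 20 cell cycle genes passed (adjusted p = 0.94), and of 13 aliphatic glucosinolate genes UGT74C1 (0.49) rose and 12 did not pass (adjusted p = 0.77). The call of UGT74C1 was lost without control mid replicate 2 or 3, UV-B mid replicate 1, 2 or 3, control late replicate 1 or 2, or UV-B late replicate 2 or 3 (log2 changes of 0.37 to 0.49) and within slide 1 (0.64). With slide as a block (adjusted p = 0.067) and with the replicate number as a block (adjusted p = 0.068) its call was lost while the change stayed at 0.49. The median and the mean differ in sign for the oxidative stress (-0.06 and 0.14) and cell cycle (-0.03 and 0.01) lists.

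Named genes at late that lost their call with the slide row as a covariate were SAG12, WRKY38, CAT1, CAT3, LOX2, ETR2, EBF2, CYP79B2, UGT74C1, LHCB2.1, CHLH, CHLI2, VTE4, NAC103, BIP3, CCA1, RVE1, CHE, ASN1, CER3, FDH and ATML1. With normexp UVR8, UGT74C1, NAC103 and ASN1 lost it too, with the mean over probes CAT1, CYP79B2 and BIP3, and with no filter on dim probes UVR8, CYP79B2, UGT74C1 and BIP3. Scaling to the median ended the call of CYP79B2, quantile scaling that of UGT74C1, and a fit of only the late groups those of CYP79B2, UGT74C1, EBF2 and BIP3. Changes that kept their call and moved by over 1.5 times were those of DDB2 (1.3), ETR2 (-0.73), LEA4-5 (-0.71), CER4 (-2.23) and HSD2 (-1.98) with normexp, and of UVR8 with the slide row (-1.18).

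Of the markers at late, the epidermal genes FDH (-0.67 ± 0.15) and ATML1 (-0.60 ± 0.12) fell and 6 of the 8 epidermis and guard cell markers did not pass (adjusted p = 0.70), with a median of 0.02 and a mean of -0.08. Within slide 1 FDH lost its call (-0.64). None of the root (adjusted p = 0.94), vascular (0.77) or meristem (0.62) markers or of the 9 reference genes (0.27) passed, nor did AG (0.10 ± 0.36) or CRU3 (0.38 ± 0.32). Adjusted over the list alone, the late counts were the same except that 14 UV-B receptor, 14 phenylpropanoid and 7 chlorophyll synthesis genes rose, 17 abscisic acid, 3 oxidative stress, 2 heat shock and 8 unfolded protein genes fell, 1 auxin gene rose and 23 fell, 2 wax genes rose and 8 fell, and 0 camalexin and aliphatic glucosinolate genes passed. With slide as a block the late medians stayed as given, because slides 1 and 2 hold both groups equally. Within slide 1 and on slide 2, respectively, they were 1.95 and 1.93 for UV-B receptor signalling, 3.89 and 3.58 for flavonoids, 0.79 and 1.00 for phenylpropanoids, 0.64 and 0.78 for photoprotection, 0.22 and 0.29 for DNA repair, 0.42 and 0.15 for chlorophyll synthesis, -2.14 and -2.39 for auxin, -1.17 and -0.48 for abscisic acid, -0.39 and -0.24 for wax, -0.53 and -0.05 for jasmonate, -0.65 and -0.51 for unfolded protein, -0.77 and -0.31 for senescence, and -0.23 and -0.43 for photosynthesis genes.

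**Figure D3:**
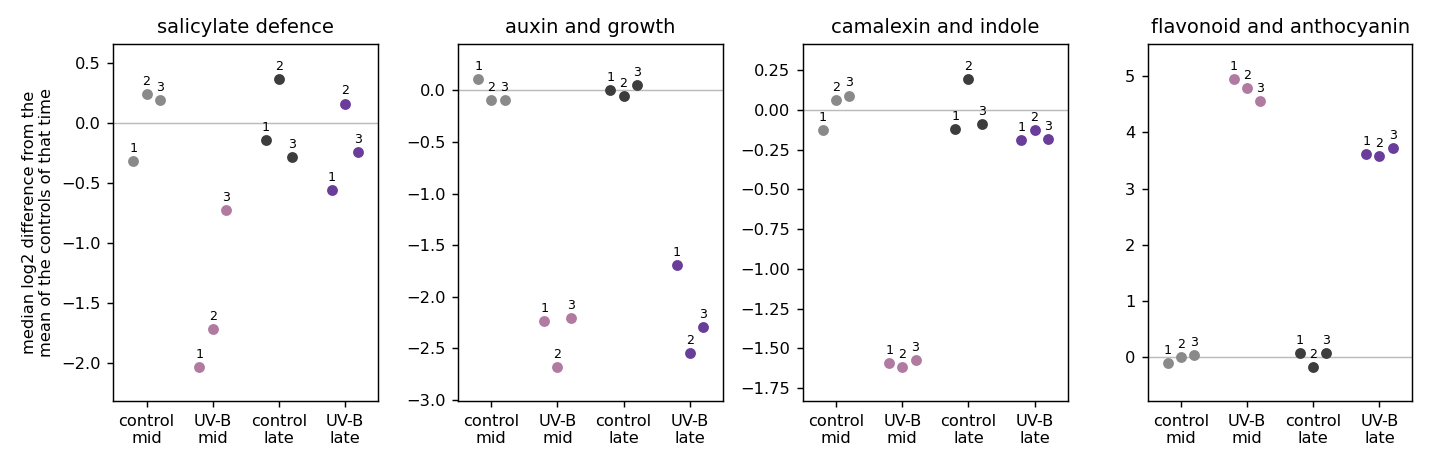
Median over the genes of 4 lists on each array, as the log2 difference from the mean of the control arrays of the same time, for the 4 groups, where a dot is an array and the number above it the replicate. The salicylate median of UV-B mid replicate 3 lay at -0.72, against -2.03 and -1.71 in replicates 1 and 2.

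The third comparison asked whether the UV-B effect differed between the time points. As lists, salicylate, camalexin and indole, ethylene and unfolded protein genes were shifted towards a less negative effect at late, and photoprotection, phenylpropanoid and clock genes towards a less positive one. The difference passed for 0 of 19 salicylate, 6 of 13 camalexin, 2 of 11 ethylene, 1 of 14 unfolded protein, 6 of 22 photoprotection, 7 of 20 phenylpropanoid and 5 of 21 clock genes. Adjusted over the list alone it passed for 4, 11, 5, 1, 6, 9 and 7 of them in the same order. Of these lists only photoprotection kept its call with an estimated correlation (adjusted p = 0.016). The adjusted p there were 0.39 for salicylate, 0.061 for camalexin, 0.19 for ethylene, 0.39 for unfolded protein, 0.061 for phenylpropanoid and 0.18 for clock genes. HY5 rose less at late than at mid (difference -1.97 ± 0.19, adjusted p = 6.6e-04), as did BCH1 (-1.78), PDX1.1 (-1.67), UGT78D3 (-3.76) and AT2G23910 (-4.82 ± 0.25), whereas ELIP2 rose more (1.27). The call of this difference for ELIP2 was lost without control mid replicate 2 or 3, UV-B mid replicate 1 or 2, control late replicate 1 or 2, or UV-B late replicate 1, 2 or 3 (1.06 to 1.35), with slide as a block (1.16), within slide 1 (1.3), with scaling to the median (1.16), with no filter on dim probes and with normexp (0.43). PAD3 (2.42), ERF1 (2.27) and MYB51 (1.99) had fallen at mid and had less negative changes at late, PAD3 with its call lost without control mid replicate 2, UV-B mid replicate 1 or 2, or control late replicate 1 or 3 (2.12 to 2.32) and with no filter on dim probes. With normexp the difference of UGT78D3 was -2.23 and that of DIN11 1.92. Large differences among genes well above background in all groups were those of AT3G23550 (4.45 ± 0.47), DIN11 (3.17), AT2G23910 and AT4G13790 (-3.89). AT3G63380, GA20OX3, of gibberellin synthesis, and BON3 had positive differences that passed, and SAG12, AT1G19500 and AT5G44440 negative ones. These 6 genes were not well above background in at least 1 group, so the size and rank of their differences are not known. The call of SAG12 was lost within slide 1 (a difference of -5.57) and with normexp background correction (-2.58), that of AT5G44440 with normexp (-0.99) and that of GA20OX3 within slide 1 (3.67). The call of BON3 was lost within slide 1 (a difference of 3.06), with normexp (0.64), with no filter on dim probes (3.20, adjusted p = 0.054) and without control mid replicate 2 (2.83), control late replicate 1 (3.26), control late replicate 3 (2.93) or UV-B late replicate 3 (3.08).

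For 875 genes the difference passed, 425 with a more positive and 450 with a more negative effect at late (48.6% more positive, but 29.2% with scaling to the median). The effect was larger at mid for 728 of the 875 and larger at late for 147, and for 331 it had opposite signs. An unadjusted p under 0.05 was reached by 3901. The count was 1330 with slide as a block, 368 within slide 1, 1496 with the slide row and 2238 with array brightness as a covariate, and 407 with no filter on dim probes. The slide block, slide 1 and the slide row all leave UV-B mid replicate 3 without weight in this difference. The 1496 with the row and the 1494 without that array therefore come from nearly the same fit. It rested on single arrays: it was 312 without control mid replicate 2, 372 without UV-B mid replicate 1, 304 without UV-B mid replicate 2, 1494 without UV-B mid replicate 3, 333 without control late replicate 1, 409 without control late replicate 3 and 511 without UV-B late replicate 3.

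Of the 26 lists, 13 differed between the times. The median differences were 1.42 for salicylate (adjusted p = 1.7e-06), 1.25 for camalexin (3.4e-10), 0.67 for unfolded protein (2.0e-04), 0.53 for ethylene (0.0017) and 0.26 for auxin genes (0.015) upwards. They were -0.67 for abscisic acid (1.5e-06), -0.48 for phenylpropanoid (1.7e-05), -0.43 for photoprotection (2.7e-06), -0.43 for clock (3.6e-04), -0.39 for UV-B receptor (0.0077), -0.29 for cell cycle (0.0080), -0.28 for wax (0.0074) and -0.25 for flavonoid genes (0.0017) downwards. Of their members, 3 of 25 auxin genes had a more positive effect that passed, 6 of 24 abscisic acid, 1 of 20 cell cycle and 2 of 14 wax genes a more negative one. Of 16 UV-B receptor genes 1 was more positive and 2 were more negative, and of 25 flavonoid genes 1 and 9. Adjusted over the list alone, 7 auxin genes were more positive and 1 was more negative, 10 abscisic acid, 1 cell cycle and 4 wax genes were more negative, 2 UV-B receptor genes were more positive and 2 more negative, and 1 flavonoid gene was more positive and 11 more negative. With an estimated correlation only photoprotection passed (adjusted p = 0.016), while the other 12 had adjusted p between 0.061 and 0.56. Fry called 9 lists, without the cell cycle (adjusted p = 0.089), salicylate (0.13), unfolded protein (0.13) and auxin (0.26) lists.

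Other settings for the lists of this difference were run after the data had been examined. The cell cycle list lost its call with slide as a block (adjusted p = 0.135), within slide 1 (0.66), with the slide row (0.052) and without control mid replicate 3 (0.053), UV-B mid replicate 3 (0.052) or UV-B late replicate 3 (0.051). The auxin list lost it without control mid replicate 1 (adjusted p = 0.053), UV-B mid replicate 2 (0.0504) or UV-B late replicate 1 (0.31), and the wax list with quantile scaling (0.099). Oxidative stress genes, which had not passed (adjusted p = 0.072), passed as less negative or more positive at late with quantile scaling (0.023), scaling to the median (0.041), the mean over probes (0.043), slide as a block (0.023) and the slide row (0.019), and without control mid replicate 1 (0.0095), UV-B mid replicate 3 (0.019) or control late replicate 2 (0.014). Aliphatic glucosinolate genes passed likewise within slide 1 (adjusted p = 0.026) and without control late replicate 3 (0.043), and chlorophyll synthesis genes with quantile scaling (0.040). Photosynthesis genes passed in the other direction without control mid replicate 3 (adjusted p = 0.033) or UV-B late replicate 1 (6.2e-04).

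Between mid and late, 3594 genes changed the same way at both times, which is 78.8% of those changed at late. Of these 2134 rose, against 527.1 if the lists of both times were independent, and 1460 fell, against 455.2. The comparisons share no arrays, but they share the estimate of each gene's spread. Genes with a small spread are therefore more easily called at both times, and the numbers for independent lists may be too low. In fits of only the groups of each comparison, 2716 genes changed the same way. For 235 of the 3594 genes the size of the effect also differed between the times, and 50 genes changed in opposite directions. Across all genes, which are not independent replicates, the changes at mid and late correlated at 0.764, and among genes changed at both times the median ratio of late to mid was 0.832. Averaged over both times, 9362 genes changed, 4595 higher and 4767 lower. Within slide 1 the count of genes changed the same way was 2185, and with slide as a block it was 3290. The averaged count was 7758 within slide 1 and 8951 with the block. With the slide row as a covariate, 1121 genes changed the same way and 2872 in the average. UV-B arrays lay in row 1 at both times except UV-B mid replicate 3, so the agreement between the times does not separate UV-B from a row effect, and the row estimate rests on that array.

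The last comparison gave the background of time in the control plants. Clock genes were among those that differed most: ELF4 was higher at late by 5.11 ± 0.18, LUX by 3.92 ± 0.11 and BOA by 3.25 ± 0.25. CCA1 was at least 19.8-fold and PRR9 at least 13.3-fold lower, both not well above background in the late controls, and LHY fell by 3.99 on the log2 scale, to a level well above background on 1 of the 3 late controls. COR27 (7.74 ± 0.13), AT4G33980 (6.33 ± 0.14), RVE2 (5.71 ± 0.16) and JMJD5 (5.56 ± 0.17) rose most, and AT1G13650 (-5.88 ± 0.33, well above background on 1 of the 3 late controls) and CIPK20 (-4.83 ± 0.23) fell, as did AT3G09450, at least 10.5-fold. Of the 21 clock genes 8 were higher and 9 lower, and the list as a whole was not shifted (adjusted p = 0.90). Auxin genes were lower in 22 of 25 cases and 3 did not pass (median -1.33, adjusted p = 1.5e-13, and adjusted p = 0.10 with an estimated correlation).

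**Figure D4:**
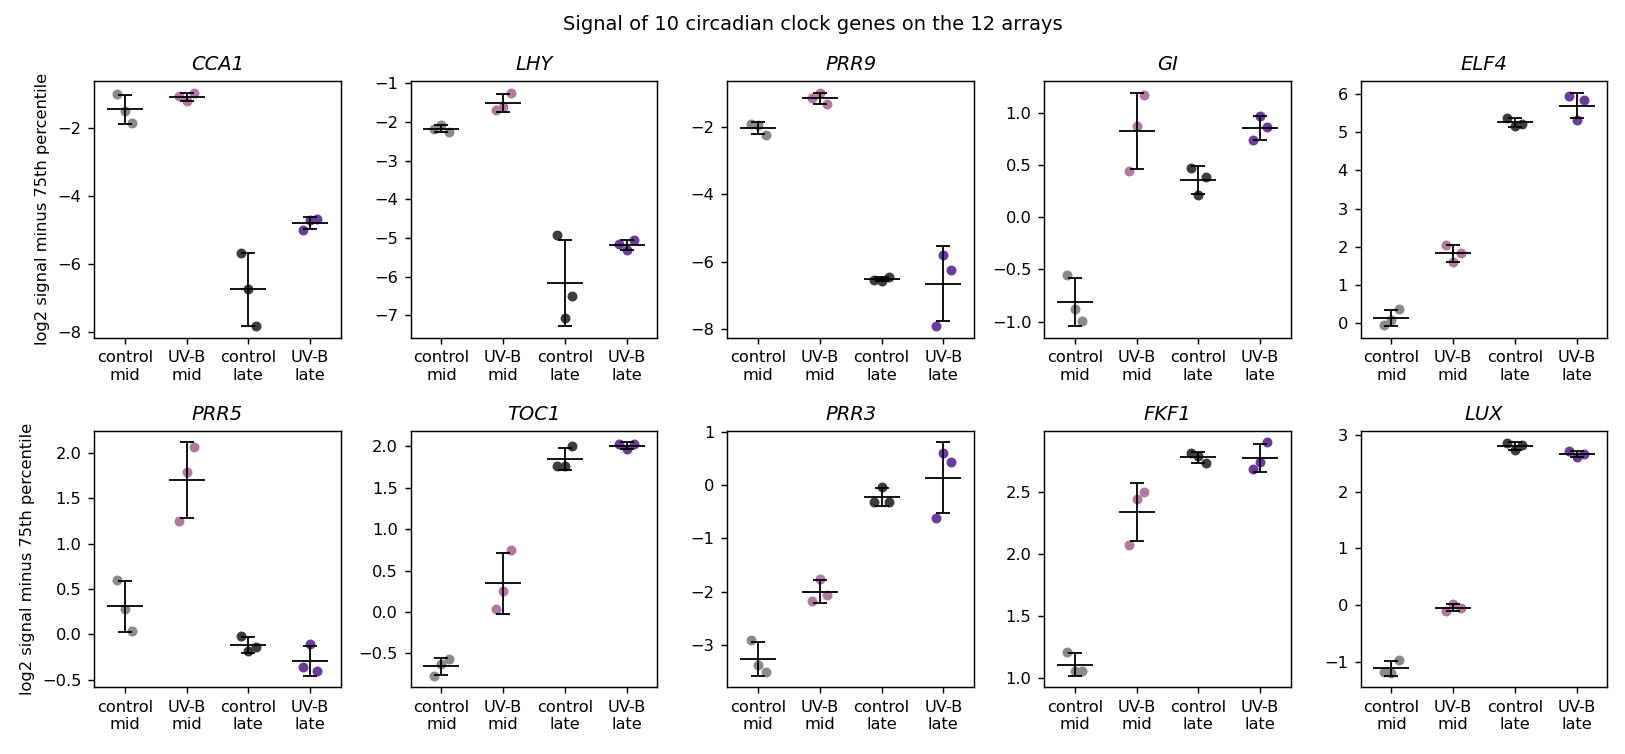
Signal of 10 clock genes in the 4 groups, as log2 intensity minus the array's 75th percentile, where a dot is an array, a black bar the mean of 3 arrays and the error bar their SD. CCA1, LHY and PRR9 were lower at late than at mid in both treatments, and ELF4, TOC1, PRR3, FKF1 and LUX were higher.

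Further lists shifted with time in the controls were UV-B receptor signalling (9 of 16 lower and 1 higher, adjusted p = 4.7e-05), chlorophyll synthesis (7 of 15 lower, adjusted p = 4.7e-05), aliphatic glucosinolates (3 of 13 lower, adjusted p = 0.0028), flavonoids (10 of 25 higher and 1 lower, adjusted p = 0.0033), photoprotection (8 of 22 lower and 4 higher, adjusted p = 0.0093), camalexin (2 of 13 lower, adjusted p = 0.025) and photosynthesis (8 of 37 lower, adjusted p = 0.042). Adjusted over the list alone, the counts were 10 lower and 2 higher for UV-B receptor genes, 8 lower for aliphatic glucosinolates, 11 higher and 3 lower for flavonoids and 10 lower and 4 higher for photoprotection, and as given for the others. None of the 8 passed with an estimated correlation, the smallest adjusted p being 0.10. Fry called 11 lists, without photosynthesis (adjusted p = 0.55) with phenylpropanoid (0.0069) and vascular (0.020) genes as lower, and with abscisic acid (0.033) and clock genes (0.0069) as higher, the latter with a mean of -0.22. In total 3304 genes differed, 1652 higher and 1652 lower (50% higher, but 61.6% with scaling to the median), and 6283 had an unadjusted p under 0.05. The count was 3238 with slide as a block and 1910 within slide 1. Without control mid replicate 1 it was 1973, without control mid replicate 2 it was 1881, without control late replicate 1 it was 1932 and without control late replicate 3 it was 2146. Among the settings run for these lists after the data had been examined, the photosynthesis list lost its call with slide as a block (adjusted p = 0.063), within slide 1 (0.43), with the slide row (0.055) and without control mid replicate 3 (0.58), UV-B mid replicate 3 (0.055) or control late replicate 2 (0.21). Camalexin lost it without control mid replicate 3 (adjusted p = 0.075) or control late replicate 1 (0.080), and photoprotection without control late replicate 2 (0.058). Phenylpropanoid genes passed as lower with normexp (adjusted p = 0.046), quantile scaling (0.044) and no filter on dim probes (0.012), and vascular markers with no filter (0.033) and without control mid replicate 2 (0.039). Abscisic acid genes passed as higher without control late replicate 3 (adjusted p = 0.038), and clock genes among those well above background on all 12 arrays (0.031). With normexp LHY stood at -1.79 and AT1G13650 at -3.06.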

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

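The tests of UV-B mid replicate 3, of the main axis of spread within groups and of the evening clock genes were chosen after the results they concern had been seen. The genes and lists in the next paragraphs stand here because limma's test of the difference between the UV-B effects at mid and late passed (adjusted p at most 0.0495).

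Among named genes the effect was more negative or less positive at late for SAG12 (-6.10), AT1G19500 (-5.67), AT2G23910 (-4.82), AT5G44440 (-4.02), AT4G13790 (-3.89), UGT78D3 (-3.76), AT4G12510 (-2.53), CER4 (-2.15), LEA4-5 (-2.09), HY5 (-1.97), AT3G62990 (-1.84), BCH1 (-1.78), PDX1.1 (-1.67), PRR5 (-1.57), RD20 (-1.55), RD22 (-1.37), 4CL3 (-1.35), UGT84A1 (-1.28), ELF4 (-1.25), FKF1 (-1.24), LUX (-1.21), VTE4 (-1.18), GI (-1.13), PHR1 (-1.04), F3H (-0.77) and CDC6 (-0.69). It was more positive or less negative at late for TT7 (0.85), CYP79B2 (1.13), ELIP2 (1.27), HSFB2A (1.56), TIN1 (1.71), YUC8 (1.77), GSTF7 (1.91), MYB51 (1.99), ERF1 (2.27), YUC9 (2.32), PAD3 (2.42), AT3G21330 (2.85), AT5G62280 (3.01), DIN11 (3.17), BON3 (3.20), GA20OX3 (3.28), AT3G63380 (3.33) and AT3G23550 (4.45). YUC8, YUC9, AT5G62280, AT3G21330, SAG12, AT4G12510, AT1G19500, AT5G44440, BON3, GA20OX3 and AT3G63380 were not well above background in at least 1 group, so the size of these differences is not known.

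Leaving out single arrays ended some of these calls. With the log2 differences in brackets, these were AT3G21330 without control mid 2 (2.75), LEA4-5 without control late 1 (-2.00), UGT84A1 without UV-B mid 1 or 2 (-1.22 and -1.21), AT5G62280 without control mid 2, UV-B mid 1 or control late 1 (2.89 to 3.06), and RD20 without control mid 2, UV-B mid 1 or 2 or control late 1 (-1.59 to -1.50). BON3 lost it without control mid 2, control late 1 or 3 or UV-B late 3 (2.83 to 3.26), ELF4 without control mid 2, UV-B mid 1 or control late 1 or 3 (-1.27 to -1.15), and PAD3 without control mid 2, UV-B mid 1 or 2 or control late 1 or 3 (2.12 to 2.32). GI lost it without control mid 2 or 3, UV-B mid 2, control late 1 or 3 or UV-B late 3 (-1.14 to -1.04), and CYP79B2 (1.05 to 1.17) and GSTF7 (1.74 to 1.87) without control mid 2 or 3, UV-B mid 1 or 2 or control late 1 or 3. AT4G12510 lost it without control mid 1 or 2, UV-B mid 1 or 2, control late 1 or 3 or UV-B late 3 (-2.62 to -2.35), CDC6 without control mid 2 or 3, UV-B mid 1 or 2, control late 1 or 3 or UV-B late 3 (-0.73 to -0.63), and YUC8 without control mid 1 or 2, UV-B mid 2 or 3, any late control or UV-B late 3 (1.48 to 1.92). ELIP2 lost it without control mid 2 or 3, UV-B mid 1 or 2, control late 1 or 2 or any late UV-B array (1.06 to 1.35), and TIN1 without control mid 2 or 3, UV-B mid 1 or 2, control late 1 or 3 or any late UV-B array (1.49 to 1.80). F3H lost it without any mid control, UV-B mid 1 or 2, control late 1 or 3 or UV-B late 2 or 3 (-0.83 to -0.68), and TT7 without any mid control, UV-B mid 1 or 2, control late 2 or 3 or UV-B late 2 or 3 (0.72 to 0.91).

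Within slide 1 the calls of GA20OX3 (3.67), BON3 (3.06), AT3G21330 (3.03), GSTF7 (1.87), TIN1 (1.55), HSFB2A (1.55), YUC8 (1.49), ELIP2 (1.3), CYP79B2 (1.25), TT7 (0.83), CDC6 (-0.62), F3H (-0.77), GI (-0.86), PHR1 (-1.04), PRR5 (-1.21), FKF1 (-1.22), VTE4 (-1.33), UGT84A1 (-1.36), ELF4 (-1.45), LEA4-5 (-2.28), AT4G12510 (-2.70) and SAG12 (-5.57) were lost. Slide as a block ended those of ELIP2 (1.16), YUC8 (1.74), TT7 (0.85), F3H (-0.77) and GI (-0.94), and as a random block that of TIN1 (1.70). With normexp background correction ELIP2 (0.43), BON3 (0.64), CER4 (-0.36), CDC6 (-0.54), LEA4-5 (-0.85), AT4G12510 (-0.92), AT5G44440 (-0.99) and SAG12 (-2.58) lost theirs. With no filter on dim probes BON3, ELIP2, YUC8, F3H, CDC6, ELF4, GI, PAD3, TIN1, GSTF7, TT7, AT4G12510 and CYP79B2 did, and with the mean over probes 4CL3 (-0.97), GI and TIN1. Scaling to the median ended the calls of ELIP2, TIN1 and TT7, quantile scaling those of YUC8, F3H and TT7, and the slide row and the trend and robust settings that of YUC8.

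Median differences of lists whose shift differed between the times were -0.39 for UV-B receptor signalling, -0.25 for flavonoids, -0.48 for phenylpropanoids, -0.29 for the cell cycle, 1.42 for salicylate, 0.53 for ethylene, 1.25 for camalexin and indole genes, -0.43 for photoprotection, 0.67 for unfolded protein, -0.67 for abscisic acid, -0.43 for the clock, 0.26 for auxin and -0.28 for wax. With an estimated correlation only photoprotection passed (adjusted p = 0.016), and the other 12 had adjusted p between 0.061 and 0.56. Probes without a locus also carried signal: of 4430 tested, 971 changed at mid, 455 at late, 3 in the difference between the times and 334 between the controls.

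The count of genes changed was compared with that of other splits of the same arrays. For mid (8290 genes), late (4559) and the controls (3304), the highest other split gave 0 genes and 1 of 10 splits, the real one, was as large, but 10 splits are too few for a share under 0.05. For the lists shifted, other splits gave as many: the real split gave 13 at mid, where 4 of 10 splits were as large and the highest other gave 16, and 13 at late, where 3 of 10 were as large and the highest other gave 13. The number of lists shifted thus does not set the real split apart from the others. Every other split still keeps most arrays of a treatment together, so part of the UV-B difference remains in it. For the lists this comparison therefore says little about chance. For the effect averaged over both times the real split was alone (9362 against 5831 at most, 1 of 100), a share under 0.05. A chance split of these arrays is thus an unlikely source of that count. The comparison does not separate UV-B from the slide row, and the arrays may not stand for separate plants. For genes changed the same way at both times the real split was also alone (3594 against 50 at most, 1 of 100). Splits of the mid or late arrays that mix the treatments called 0 genes, however, so hardly any such genes could arise in them. The split with 50 keeps mid and exchanges all late labels, which turns opposite changes into same-way ones. This test therefore does not decide on the agreement between the times. For the 875 genes whose effect differed between the times, 7 of 100 splits were as large, so this count does not exclude chance. The 5 highest (9362, 5309, 4803, 4214 and 2265) keep the mid labels and move 4 or 6 late arrays, which carries the averaged UV-B effect into the difference. The count of 7 therefore says little about chance either way.

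Salicylate genes of UV-B mid replicate 3 lay at a median of -0.72, against -2.03 and -1.71 in replicates 1 and 2, and it stood apart likewise for unfolded protein (-0.73 against -1.63 and -1.56) and senescence genes (0.10 against -0.81 and -0.91), for which no explanation was tested. The tables argue against control RNA in its place, since its flavonoid genes kept 95.6% of their change, and against an admixture of control RNA, since its auxin genes were 0.790% of the way back to the control (upper quartile 3.23%) where 38.3% was needed. They argue against the row of the array as the whole cause, since the late UV-B arrays, in the other row, reached at most 29.6% of the fall of -1.87. The slide cannot be told apart from the sample, because 0 other arrays lay on it. A biological difference of these plants was not tested and stays open.

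The main axis of spread within groups held 41.4% of that variance and followed the brightness of the 12 arrays, centred within groups (r = 0.925, rank correlation 0.909). The permutation p was 1e-05, the smallest that 1e+05 draws allow. These draws exchanged arrays between groups although the values were centred within groups, so this p is not exact and may be too small. Root markers (-0.98), photosynthesis genes (-0.72, or -0.36 with the signal level removed) and meristem markers (-0.54, or -0.31 likewise) had negative and salicylate (0.65) and senescence genes (0.58) positive median loadings. A bias that depends on signal level explained 6.57% of the loadings, and 51.8% of the axis lay between arrays of the same group on slide 1, which argues against each of these as the whole cause. RNA amount or quality was not measured here and stays open, and no biological explanation was tested.

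Evening clock genes (GI, ELF4, PRR5, TOC1, PRR3, FKF1 and LUX) had a median change of 1.26 at mid. CCA1, LHY and PRR9, which fall with time in the controls, had a median of 0.656 at mid. Their changes were 0.37 ± 0.41, 0.66 ± 0.40 and 0.89 ± 0.40. None passed limma's test (adjusted p = 0.51, 0.22 and 0.097). Between the controls CCA1 fell at least 19.8-fold, LHY changed by -3.99 on the log2 scale and PRR9 fell at least 13.3-fold. The mid values argue against sampling of the UV-B plants as late as the late time point. They do not decide on a shorter delay, because the fall it would give was not estimated. The slide is argued against by a median of 1.15 for the evening genes within slide 1. An effect of UV-B on the evening genes remains a hypothesis, found and tested on the same arrays.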

How the results depend on the processing

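The array brightness covariate, the replicate block with only the groups compared, and all settings for the lists of the difference and of the controls and for most genes of the difference were chosen after the data had been seen. Of the counts, 196 stayed within 1.5 times the first value and 30 moved. For named genes 6263 results stayed on their side of the threshold, 441 lost and 8 gained a call, and for lists 2801 stayed, 85 lost, 44 gained and 4 reversed. Most named genes were chosen for large changes in the first fit, where 225 of 245 results passed, so few could gain a call. The authors' table holds nearly the same values up to a constant per probe, so its agreement was largely fixed in advance. Against 875 genes, the difference between the times gave 407 with no filter on dim probes and 1330 with slide as a block; the cause was not tested. Within slide 1, which has fewer arrays, late gave 2858 genes (4559 with all), the difference 368, the controls 1910 (3304 with all) and the same way at both times 2185 (3594 with all). With the slide row as a covariate, which rests on 1 array, mid gave 4642 (8290 without it), late 1369, the difference 1496, the average of both times 2872 (9362 without it) and the same way at both times 1121. The salicylate list at late reversed to a mean of 0.85 and the unfolded protein list to 0.19 under it. The clock list of the controls passed as higher with a mean of 0.88 among genes well above background on all 12 arrays and as higher with fry despite a mean of -0.22. Requiring at least a 2-fold change, which removes small changes by construction, left 3181 at mid, 1514 at late, 1157 in the controls and 2119 in the average. An estimated correlation left 4 lists at mid and 5 at late, against 13 each. With array brightness as a covariate late gave 6947 and the difference 2238; the cause was not tested. Leaving out 1 array each gave 6599 to 9275 at mid, 3054 to 5809 at late, 304 to 1494 for the difference, 1881 to 4772 for the controls, 8269 to 10178 for the average, 2572 to 4264 for the same way and 11 to 14 lists at each time.

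With the replicate number as a block the counts were 8281 at mid, 4528 at late, 853 for the difference, 3371 for the controls, 9450 for the average, 3523 for the same way and 13 lists at each time. For the difference the block ended the calls of F3H (-0.77), GI (-1.13) and TT7 (0.85). At late the block ended the call of CYP79B2 (adjusted p = 0.062) and that of UGT74C1 (0.068). Apart from these, the block in the fit of all groups ended no call of a named gene or a list at late and moved no count by over 1.5 times. The mid groups share only a number; there TTG1 was no longer called (0.065), nor were MCM3 (0.060) and SUC2 (0.067). With only the groups compared, the block gave 6210 genes at mid and 4163 at late, and 13 and 14 lists. At late this form ended the calls of CYP79B2 (0.063), UGT74C1 (0.099) and EBF2 (0.070), and PR1 (0.0024) and the salicylate list (0.016) passed. At mid it ended those of 12 genes and of the cell cycle list (0.054), and the photosynthesis list passed (0.038). It could not be applied in that form to the difference or the average. The random block for slide was not run for lists, because camera takes no block. Signal over background limits genes that were dim in 1 group, whose changes are bounds.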

Other observations

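For this part 22 gene families were chosen by name after the data had been seen, leaving out members of the lists fixed beforehand. None of them passed with an estimated correlation. Only families that passed at mid or late with the preset correlation are described, and the others passed at neither time. At mid, cysteine-rich receptor-like kinase genes fell in 16 of 20 cases and 0 rose (median -1.35, or -0.77 with normexp background correction, adjusted p = 3.6e-05, and adjusted p = 0.66 with an estimated correlation). WRKY transcription factor genes fell in 23 of 50 cases and 3 rose (median -0.59, or -0.33 with normexp, adjusted p = 9.9e-04, and 0.52 with an estimated correlation). At late, 3 of the kinase genes fell (median -0.13, or -0.08 with normexp, adjusted p = 0.25), and 4 WRKY genes fell and 2 rose (adjusted p = 0.54).

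SAUR genes, known for their response to auxin, fell in 27 of 52 cases at mid and 4 rose (median -1.04, or -0.46 with normexp, adjusted p = 3.0e-06, and 0.66 with an estimated correlation), and at late 25 fell and 2 rose (median -0.80, adjusted p = 2.1e-09, and 0.57 with an estimated correlation). Tubulin genes fell in 6 of 15 cases at mid (median -0.40, adjusted p = 0.032, and 0.66 with an estimated correlation) and in 8 at late (median -0.47, adjusted p = 0.0016, and 0.57 with an estimated correlation). Of 25 genes of xyloglucan-modifying enzymes 10 fell and 2 rose at late (median -0.31, or -0.18 with normexp, adjusted p = 0.018, and 0.59 with an estimated correlation), and of 40 arabinogalactan protein genes 8 fell and 1 rose (median -0.30, adjusted p = 0.0050, and 0.71 with an estimated correlation). Neither was shifted at mid (5 higher and 8 lower, adjusted p = 0.40, and 4 higher and 5 lower, adjusted p = 0.40). At late, cytochrome P450 genes fell in 35 of 136 cases and rose in 6 (adjusted p = 9.5e-04, and 0.57 with an estimated correlation), aquaporin genes fell in 4 of 21 (adjusted p = 0.030, and 0.71), and ABC transporter genes rose in 15 of 92 and fell in 8 (median 0.18, adjusted p = 0.034, and 0.71). At mid these were not shifted: 48 P450 genes fell and 25 rose (adjusted p = 0.11), 1 aquaporin gene fell and 3 rose (0.59), and 18 ABC transporter genes fell and 23 rose (0.63). Of 10 genes matched by name as basic helix-loop-helix genes, 6 fell at mid (adjusted p = 0.010, and 0.66) and 4 at late (adjusted p = 0.0054, and 0.57). Members of that family with other names were not included.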
